A study of Arabidopsis thaliana with 27 samples.

How the data were processed

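RNA of whole Arabidopsis thaliana seedlings was sequenced in 27 libraries, 3 for each of 9 combinations of genotype and time of day. Per the labels' protocols, plants stood on MS medium at 22 °C for about a week in short days of 8 h light and 16 h dark, RNA was prepared with a Qiagen plant kit, and 1 µg of it went into a strand-marking NEBNext library. Zeitgeber time (ZT) counts hours from lights on, so that ZT0 is the end of the night and ZT6 lies 6 h into the light. Each library came as a deposited table of whole-number read counts per gene, which the authors had not normalised. Per the submitters' processing notes, FastQC, STAR and edgeR were used with the TAIR10 genome, without versions; the strand setting of the counting step is not given in the sources used here. Without that setting, reads of a gene and of its antisense partner cannot be told apart.

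Every table listed 32678 gene identifiers and 5 lines that name no gene, such as reads outside genes, reads placed at several sites and ambiguous reads. Those lines stayed out of library sizes and tests. Reads in genes made up 90.8 to 96.2% of the reads in a table, ambiguous reads 0.690 to 0.993%. Reads outside genes made up 0.586 to 1.12% in the 24 libraries of the other lines and 2.16 to 2.89% in hy5, and reads placed at several sites made up 2.45 to 4.35% and 4.32 to 5.42%. The 279 genes of the chloroplast and mitochondrion had 0 reads in all libraries. Gene names came from a reference gene table of the TAIR10.1 assembly, which matched 31912 identifiers. Since that release differs from the one the submitters name, the table served only for names, gene types and neighbours, and no coordinates are printed.

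Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr over the 9 groups, which left 21448. Library sizes were scaled by TMM, and levels are given as CPM on those scaled sizes, as mean ± SD with n = 3. A quasi-likelihood model with robust dispersion and 1 coefficient per group (18 residual degrees of freedom) gave log2 fold changes with standard errors (SE) for each contrast. Benjamini-Hochberg adjustment ran over all 21448 genes of a contrast at 0.05, and every adjusted p of a gene below comes from this edgeR quasi-likelihood test. The labels number the replicates but do not say that they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Before the data were examined, the groups, the model, the gene lists, the rule for named genes and the alternative settings were fixed.

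Where all libraries of a group had 0 reads of a gene, its fold is given as at least the value against a floor of 3 counts over the group. With 1 to 3 reads in a group, the ratio is given with its 95% exact Poisson counting interval in place of the fitted value. Such floors and intervals cover counting error only.

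The rule for named genes took COP1, VIL1 and HY5 in each contrast. It added up to 5 genes on each side with the largest change among called genes with a symbol and a mean of at least 5 CPM, for which each replicate of one group lay above each replicate of the other in contrasts of a pair of groups. From each gene list it took up to 4 called members on each side with the smallest p. Of the kept genes, 9152 had a symbol. Genes that the rule names in a contrast may be followed in others.

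There were 20 gene lists: photoreceptors and COP1-SPA; photomorphogenesis regulators; flavonoid and anthocyanin synthesis; PIF, shade and elongation; auxin response and transport; gibberellin and brassinosteroid metabolism; circadian clock; flowering time; Polycomb target developmental genes; Polycomb and VIN3-like components; light harvesting and photosynthesis; chlorophyll synthesis; night and low-energy genes; cold response; defence; glucosinolate synthesis; stomatal lineage; root markers; seed storage and embryo markers; and cell cycle. The last 4 stand for tissues and cell types whose share could differ between lines. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 20 lists of a contrast, with an estimated correlation beside it. Members were counted as higher, lower or not past the threshold over all genes, and also adjusted over the list alone.

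Of 334 named genes found in the gene table, 83 overlap another annotated gene, among them CHS, FLC, THA1, COR15B, GPX7, ORP4C, CKX5, UGT75C1, GSTF12, OLE1 and OLE2, and their counts are uncertain to that extent. Counts of near-identical copies are uncertain too: LHCB1 and RBCS members, SAUR genes, CBF2 and CBF3, COR15A and COR15B, MAF4 and MAF5, VSP1 and VSP2, the 2S albumins, BGLU34 and BGLU35, and the SADHU elements.

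Each pair of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.32 to 8.18, so every library counted as 1 replicate. The method was tested on simulated counts drawn from the real means, with 67, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. For vil1-1 against Col-0 at ZT0, edgeR recovered 65.7, 83.6 and 100% of them among 21031 genes, and false calls made up 6.74% of all calls. For the interaction of vil1-1 and cop1-4 at ZT0, it recovered 41.8, 71.6 and 89.4% among 21038 genes, with 2.17% false calls. The simulated groups were otherwise alike. These rates may thus not hold where most genes differ, as in cop1-4 against Col-0 at ZT0, with 68.5% of genes called. Alternatives were DESeq2 1.42.0 (Wald test), its size factors within edgeR, no filter, a stricter filter of at least 1 CPM in at least 3 libraries, a fit of the compared groups alone, the replicate number as a block, removal of the organelle genes, and leaving out each library in turn. A fit without the hy5 libraries was added after seeing the data. Correlations of log2 fold changes are across genes, which are not independent replicates, so no p is given; the 8 relations computed are all reported, and comparisons that share Col-0 libraries are set beside 20 simulations of unchanged groups against the same controls.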

Results

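The series compared wild-type Arabidopsis (Col-0) with lines mutant in light signalling or chromatin regulation. COP1 is an E3 ubiquitin ligase that marks light-signalling transcription factors, HY5 among them, for degradation in the dark. VIL1, also called VRN5, is a PHD-finger protein that acts with Polycomb repressive complex 2, the complex that methylates histone H3 at silenced genes. Col-0, vil1-1, cop1-4 and the vil1-1 cop1-4 line were each sampled at ZT0 and ZT6, and hy5, 1 mutant line whose allele number the axis labels of the figures give, at ZT0 alone, with 3 libraries per group and 27 in all. Reads in genes numbered 19.7 M to 33.6 M per library, with a median of 23 M. The first 3 principal components of the log2 CPM held 37.6, 33.1 and 11% of the variance. On the first, cop1-4 and the vil1-1 cop1-4 line lay above Col-0 and vil1-1 of the same time, and on the third hy5 lay at −78.7 to −73.4 and the other groups at −33.3 to 47.7. The hy5 samples were accessioned apart from the rest, and no label gives a batch, so a batch and this genotype cannot be told apart.

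VIL1 (AT3G24440) stood at 16.3 ± 0.343 CPM at ZT0 and 23.1 ± 1.01 at ZT6 in Col-0, and at 5.12 ± 0.348 and 5.93 ± 1.19 in vil1-1 (mean ± SD, n = 3). The log2 change in vil1-1 was −1.67 ± 0.10 (SE) at ZT0 and −1.96 ± 0.10 at ZT6, with edgeR adjusted p = 6.7e-16 and 5.8e-19. In the vil1-1 cop1-4 line VIL1 was at 5.54 ± 0.455 and 5.87 ± 0.235 CPM, −1.55 ± 0.11 and −1.98 ± 0.10 against Col-0 (edgeR adjusted p = 1.8e-16 and 1.3e-20). COP1 (AT2G32950) was at 34.3 ± 1.43 and 32.9 ± 2.39 CPM in Col-0, 47.8 ± 3.34 and 21.9 ± 1.69 in cop1-4, and 48.1 ± 3.51 and 20.8 ± 2.62 in the vil1-1 cop1-4 line. It rose by 0.48 ± 0.07 in cop1-4 at ZT0 and changed by −0.59 ± 0.08 at ZT6 (edgeR adjusted p = 2.2e-07 and 1e-08). In the vil1-1 cop1-4 line it changed by 0.49 ± 0.07 and −0.67 ± 0.08 (edgeR adjusted p = 1.3e-07 and 2.4e-10). HY5 (AT5G11260) was at 18.8 ± 0.928 CPM in Col-0 and 14.5 ± 0.111 in hy5 at ZT0, a change of −0.37 ± 0.09 (edgeR adjusted p = 0.00085). COP1 in cop1-4 and HY5 in hy5 were still read, so these counts do not test the labels of those lines.

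Outside their own mutants the same 3 genes moved little in vil1-1: COP1 by 0.00 and 0.08 and HY5 by 0.01 and 0.10 at ZT0 and ZT6 (edgeR adjusted p = 0.99, 0.5, 0.98 and 0.47). In cop1-4 HY5 changed by 0.03 ± 0.09 at ZT0 and −0.46 ± 0.10 at ZT6 (edgeR adjusted p = 0.78 and 4.2e-05), and in the vil1-1 cop1-4 line by −0.06 and −0.68 (edgeR adjusted p = 0.54 and 2.4e-08). VIL1 changed by 0.16 in cop1-4 at ZT0 (edgeR adjusted p = 0.13) and by −0.31 at ZT6 (adjusted p = 0.0028); without cop1-4 ZT6 replicate 3 the latter was −0.23 with edgeR adjusted p = 0.05. In hy5 COP1 changed by −0.26 and VIL1 by −0.06 (edgeR adjusted p = 0.0048 and 0.62).

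**Figure D1:**
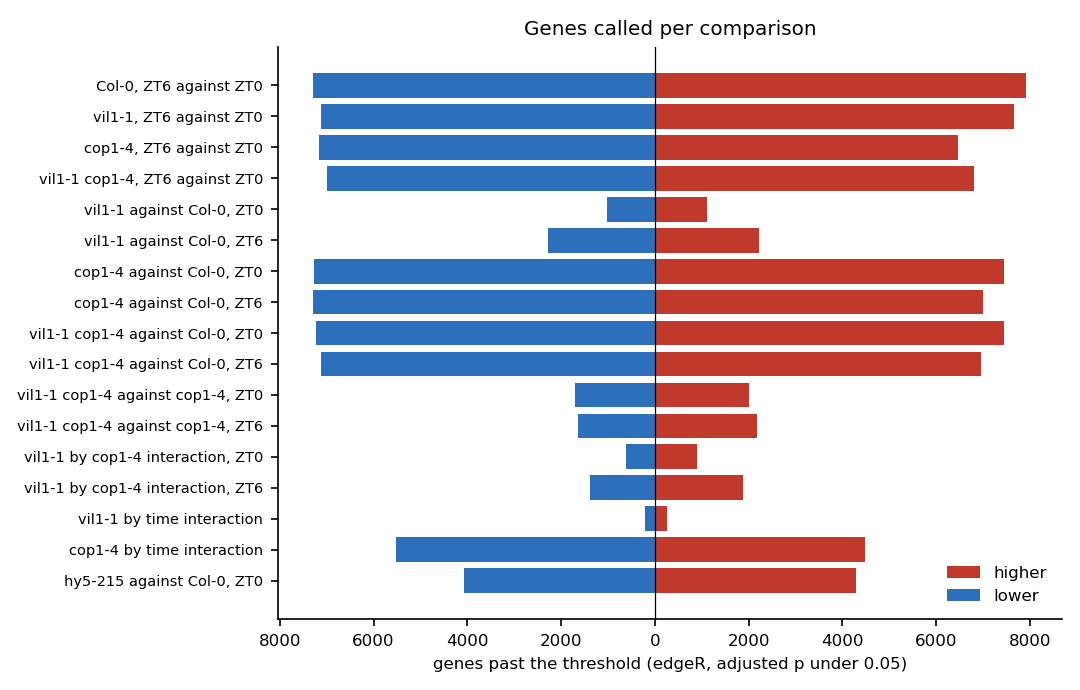
Number of genes called higher (bars to the right of 0) and lower (bars to the left) in each comparison by edgeR at an adjusted p under 0.05, of 21448 tested. The bars run from 480 genes for the interaction of vil1-1 with time to 15208 for ZT6 against ZT0 in Col-0.

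ZT6 was set against ZT0 in Col-0 to measure the shift from the end of the night into the light. The dawn clock genes LHY and CCA1, which encode MYB-related repressors, fell 750-fold and 97.9-fold (log2 −9.55 ± 0.12 and −6.61 ± 0.09 SE, edgeR adjusted p = 5.3e-38 and 1.9e-41). FKF1, a blue-light receptor of the flowering pathway, rose 639-fold and ELF4, a member of the evening complex, 251-fold (log2 9.32 ± 0.17 and 7.97 ± 0.15, edgeR adjusted p = 6.9e-35 and 5.1e-37). The cold-induced chloroplast proteins COR15B and COR15A rose 685-fold and 292-fold, from 0.153 ± 0.0579 to 111 ± 13.2 CPM and from 0.559 ± 0.243 to 161 ± 24.1 CPM (n = 3). CHS, chalcone synthase at the entry of flavonoid synthesis, rose from 11.3 ± 2.39 to 412 ± 10.5 CPM (36.2-fold, edgeR adjusted p = 2e-15). In all, 15208 genes changed, 7922 higher and 7286 lower, and 5535 of them at least 2-fold. The higher genes were 52.1% of these, and 49.6% in a fit of the compared groups alone.

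By group, 22 of 26 flavonoid genes rose and 2 fell in Col-0 (camera adjusted p = 1.2e-05; adjusted p = 0.2 with an estimated correlation), led by UGT78D1 (3.39-fold), 4CL3 (11.6-fold) and DFR, which makes leucoanthocyanidins (171-fold). All 10 cold genes rose (camera adjusted p = 0.00011; adjusted p = 0.2 with an estimated correlation), RD29A 26.5-fold and CBF3, an activator of the cold regulon, 97.7-fold. Of 12 glucosinolate genes 10 rose and 2 fell (camera adjusted p = 0.005; adjusted p = 0.2 with an estimated correlation), among them MYB29, a regulator of aliphatic glucosinolates (70-fold), and MAM1, which elongates their methionine chain (27-fold). All 7 cell cycle genes rose (camera adjusted p = 0.0024; adjusted p = 0.24 with an estimated correlation). Of 26 light-harvesting and photosynthesis genes 19 rose and 4 fell (camera adjusted p = 0.0024; adjusted p = 0.61 with an estimated correlation), with LHCA1 up 2.74-fold.

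Falling groups were the PIF, shade and elongation genes, 24 of 31 down and 3 up in Col-0 (camera adjusted p = 0.00031; adjusted p = 0.2 with an estimated correlation). IAA29 fell 9.84-fold, ATHB2 7.69-fold and PIF5, a growth-promoting bHLH factor, 2.91-fold, while PIF7 rose 3.1-fold. All 11 night and low-energy genes fell (camera adjusted p = 1.2e-05; adjusted p = 0.24 with an estimated correlation), with the trehalose-phosphate synthase genes TPS8 4.47-fold and TPS9 4.77-fold lower. The auxin list had 15 members down and 5 up of 23 (camera adjusted p = 0.0093; adjusted p = 0.24 with an estimated correlation), with GH3.5 and PIN3, an auxin exporter, 4.2-fold and 3.76-fold lower. Of 30 clock genes 13 rose and 15 fell (camera adjusted p = 0.39), RVE8 90.2-fold down and PRR5 79.4-fold up. Chlorophyll synthesis genes went both ways, 4 up and 6 down of 11 (camera adjusted p = 0.5): PORB, a light-dependent reductase, rose 11.4-fold and HEMA1 fell 3.19-fold. The counts in Col-0 were the same adjusted over the list alone, except that 23 flavonoid genes rose. COP1 changed by −0.06, VIL1 by 0.50 ± 0.09 and HY5 by −0.30 ± 0.09 (edgeR adjusted p = 0.46, 3.4e-06 and 0.0023).

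The same change was measured in the other lines. LHY fell 651-fold in vil1-1, 800-fold in cop1-4 and 618-fold in the vil1-1 cop1-4 line (edgeR adjusted p = 5.2e-38, 1.4e-37 and 6.4e-38), and CCA1 fell 145-fold, 176-fold and 134-fold. FKF1 rose 757-fold, 120-fold and 95.7-fold; its ZT0 level was 0.105 ± 0.028 CPM in Col-0 and 0.905 ± 0.229 in cop1-4. CHS, which rose in Col-0, fell in cop1-4 from 219 ± 6.7 to 117 ± 29.9 CPM (log2 −0.91 ± 0.15, edgeR adjusted p = 3.2e-05). In total 14772 genes changed in vil1-1 (7660 higher), 13627 in cop1-4 (6469 higher) and 13796 in the vil1-1 cop1-4 line (6800 higher). The shares of higher genes, 51.9, 47.5 and 49.3%, were 50 to 52.2, 47.4 to 52.5 and 49.3 to 52.2% under other settings; they were 51.6 to 52.5% in cop1-4 and 51.3 to 52.2% in the vil1-1 cop1-4 line without any single 1 of the 6 libraries of the line, and 50.6 and 50.9% with DESeq2 size factors.

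Of the flavonoid genes, 20 rose and 2 fell in vil1-1 (camera adjusted p = 0.00015; adjusted p = 0.17 with an estimated correlation), whereas 7 rose and 10 fell in cop1-4 (camera adjusted p = 0.67). PAL2 and UGT78D2 fell 3.08-fold and 2.43-fold in cop1-4, and FLS1, flavonol synthase, rose 2.14-fold. Photomorphogenesis regulators fell in 16 of 20 cases and rose in 3, both in cop1-4 (camera adjusted p = 1e-04; adjusted p = 0.09 with an estimated correlation) and in the vil1-1 cop1-4 line (camera adjusted p = 1.5e-05; adjusted p = 0.047 with an estimated correlation). In cop1-4 the B-box gene BBX25 fell 18.8-fold, and SPA3, a partner of COP1, 4.37-fold. Photoreceptor and COP1-SPA genes fell in 12 of 15 cases and rose in 3 in cop1-4 (camera adjusted p = 0.0032; adjusted p = 0.24 with an estimated correlation). Cold genes rose in 9 of 10 cases in cop1-4 (camera adjusted p = 1e-04; adjusted p = 0.092 with an estimated correlation), with COR15B up 276-fold in vil1-1, 214-fold in cop1-4 and 174-fold in the vil1-1 cop1-4 line. Defence genes rose in 8 of 11 cases in the vil1-1 cop1-4 line, with 0 lower (camera adjusted p = 0.0068; adjusted p = 0.078 with an estimated correlation). These counts were the same adjusted over the list alone, except 17 photomorphogenesis regulators and 1 defence gene lower in the vil1-1 cop1-4 line.

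COP1 itself fell between the times in cop1-4 and the vil1-1 cop1-4 line, by −1.12 ± 0.08 and −1.22 ± 0.08 (edgeR adjusted p = 9.4e-17 and 2.9e-18), and HY5 by −0.80 ± 0.10 and −0.92 ± 0.09 (edgeR adjusted p = 1.4e-09 and 1.9e-11). VIL1 changed by 0.04 and 0.08 there (edgeR adjusted p = 0.75 and 0.61). In vil1-1 COP1 changed by 0.02 (edgeR adjusted p = 0.8). VIL1 changed by 0.21 in vil1-1 (edgeR adjusted p = 0.099, but 0.36 and 0.0063 without vil1-1 ZT6 replicate 1). HY5 changed by −0.21 in vil1-1 (edgeR adjusted p = 0.031); without vil1-1 ZT0 replicate 1 or 2 the adjusted p was 0.094 and 0.19, and without vil1-1 ZT6 replicate 1 or 3 it was 0.081 and 0.086.

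vil1-1 was compared with Col-0 to see which genes depend on VIL1 at each time. At ZT0, QQS, an orphan gene that affects starch content, rose 83.1-fold, from 0.382 ± 0.146 to 32.8 ± 1.45 CPM (log2 6.38 ± 0.22, edgeR adjusted p = 1.2e-19). BSU1, a phosphatase of brassinosteroid signalling, fell 18.9-fold and BGLU34, a myrosinase, 13.9-fold (log2 −4.24 ± 0.20 and −3.80 ± 0.14, edgeR adjusted p = 6.4e-20 and 6.7e-21). QQS was also higher and BSU1 lower in cop1-4 and hy5 at ZT0, so these changes are not particular to vil1-1. The flowering repressors FLC, MAF4 and MAF5 rose 1.62-fold, 2.43-fold and 3.14-fold, and the flowering activator SOC1 fell 2.47-fold (edgeR adjusted p = 2.1e-07, 4.1e-07, 9e-06 and 1.3e-06). CRA1, a 12S seed storage globulin, rose 25.2-fold to 11.2 ± 5.09 CPM. At ZT0 2139 genes changed, 1114 higher and 1025 lower, and 441 at least 2-fold.

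At ZT0 the PIF, shade and elongation list had 9 of 31 members higher and 0 lower in vil1-1, or 12 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.8e-05; adjusted p = 0.098 with an estimated correlation). They included CKX5, a cytokinin oxidase (4.06-fold), the wall enzyme XTH15 (2.43-fold) and PAR1 (1.42-fold). Of 10 cold genes 5 rose, KIN1 4.63-fold and COR15A 3.77-fold (camera adjusted p = 8.8e-05; adjusted p = 0.078 with an estimated correlation). Of 12 glucosinolate genes 3 fell, 5 adjusted over the list alone (camera adjusted p = 0.00066; adjusted p = 0.078 with an estimated correlation), with MAM1 11-fold and the cytochrome P450 CYP83A1 6.89-fold lower. CYP79F1, which starts aliphatic glucosinolate synthesis, had 0 reads in vil1-1 and was at least 12-fold lower. Of 17 genes on the Polycomb and VIN3-like list, VIL1 itself and EMF1 fell, the latter 1.54-fold (camera adjusted p = 0.009, and 0.078 with an estimated correlation). The fall of VIL1 is given by the genotype, and the list was not tested without it. The median log2 change of the list was −0.04. Of 12 Polycomb target developmental genes 2 rose (camera adjusted p = 0.36). Seed storage and embryo markers rose in 3 of 8 cases, 4 adjusted over the list alone (camera adjusted p = 0.0042; adjusted p = 0.17 with an estimated correlation), with OLE1, an oil-body protein, and EM1 up 4.4-fold and 2.82-fold. The counts for the cold and Polycomb lists were the same adjusted over the list alone.

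At ZT6 in vil1-1, QQS rose 95.7-fold (log2 6.58 ± 0.27, edgeR adjusted p = 1.1e-17), and BGLU34 and BSU1 fell 12.7-fold and 10.5-fold (edgeR adjusted p = 7.8e-20 for each). M17, a late-embryogenesis gene, rose 6.65-fold to 125 ± 15.8 CPM, and ICL, isocitrate lyase of the glyoxylate cycle, rose 5.56-fold. MAF5 rose 6.33-fold, MAF4 2.86-fold and FLC 1.84-fold, and SOC1 fell 2.16-fold (edgeR adjusted p = 9.1e-11, 2.4e-08, 3e-09 and 1.2e-08). MAM1 fell 4.5-fold and CYP79F1 7.16-fold, from 170 ± 34.6 to 23.6 ± 5.2 CPM. At ZT6 4500 genes changed, 2223 higher and 2277 lower, and 672 at least 2-fold. Higher genes made up 49.4%, but 51.5% without Col-0 ZT6 replicate 1 and 50.9 and 51% without vil1-1 ZT6 replicate 1 or 2, and 48.5 to 52.5% over all other settings.

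Night and low-energy genes rose in 9 of 11 cases at ZT6 in vil1-1 (camera adjusted p = 1.1e-12; adjusted p = 0.076 with an estimated correlation), among them DRM1, a dormancy-associated gene (2.51-fold), TPS10 (1.52-fold) and TPS11 (1.44-fold). Flavonoid genes fell in 14 of 26 cases and 1 rose, with 17 lower adjusted over the list alone (camera adjusted p = 5.1e-06; adjusted p = 0.12 with an estimated correlation). GSTF12, needed for anthocyanin transport, fell 4.95-fold, UGT75C1 3.23-fold and UGT79B1 3.91-fold, and MYBL2, a repressor of the pathway, rose 1.78-fold. Glucosinolate genes fell in 10 of 12 cases and 1 rose (camera adjusted p = 8e-05; adjusted p = 0.076 with an estimated correlation), with SUR1 1.83-fold and BCAT4 4.71-fold lower. Defence genes fell in 5 of 11 cases, 6 adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.12 with an estimated correlation), with VSP1 1.7-fold, LOX2 1.91-fold and PR5 2.12-fold lower. Cold genes rose in 7 of 10 cases (camera adjusted p = 0.002; adjusted p = 0.12 with an estimated correlation), cell cycle genes fell in 5 of 7 (camera adjusted p = 0.0081; adjusted p = 0.19 with an estimated correlation) and chlorophyll synthesis genes fell in 5 of 11, 6 adjusted over the list alone (camera adjusted p = 0.0015; adjusted p = 0.2 with an estimated correlation). COR15B rose 2.42-fold, and CAO, which makes chlorophyll b, fell 1.36-fold. Seed storage and embryo markers rose in 5 of 8 cases, 6 adjusted over the list alone (camera adjusted p = 0.00091; adjusted p = 0.12 with an estimated correlation). The night, glucosinolate, cold and cell cycle lists had the same counts adjusted over the list alone.

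Polycomb target developmental genes rose in 4 of 12 cases at ZT6 in vil1-1 and 1 fell (camera adjusted p = 0.046; adjusted p = 0.12 with an estimated correlation), with FLC among the higher and SEP3, a floral MADS factor, 4.02-fold lower. That call was lost without Col-0 ZT6 replicate 2 or vil1-1 ZT6 replicate 3 (camera adjusted p = 0.066 and 0.11; 0.036 to 0.12 over all other settings). Of 17 genes on the Polycomb and VIN3-like list 4 fell, VIL1 itself and EMF1 (1.57-fold) among them, and 1 rose (camera adjusted p = 0.041, and 0.12 with an estimated correlation). This call was lost without Col-0 ZT6 replicate 3 (camera adjusted p = 0.054; 0.028 to 0.17 over all other settings). Both lists had the same counts adjusted over the list alone. The second list holds VIL1, whose fall is given by the genotype, and it was not tested without VIL1. Its median log2 change was −0.04 at ZT6.

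The effects of vil1-1 at ZT0 and ZT6 correlated across genes with Pearson's r = 0.573 and Spearman's rho = 0.47, and these comparisons share no library; r was 0.261 with no filter on low counts and 0.677 in a fit of the compared groups alone. Of 1292 genes called at both times, 717 were higher at both, 559 lower at both and 16 opposite, where independent lists would share 115.5 and 108.8. A test of the difference between the times called 480 genes, 266 with a more positive and 214 with a more negative effect at ZT6. Chance was not excluded. In fits of these 4 groups alone 1111 were called with the real split and 1209 with another. The other splits mix libraries of lines that differ, so the 1209 does not measure what chance would give. Night and low-energy genes had a higher effect at ZT6 in 7 of 11 cases, 10 adjusted over the list alone (camera adjusted p = 1.5e-15; adjusted p = 0.074 with an estimated correlation), TPS11 by 0.62 ± 0.10 and TPS10 by 0.50 ± 0.09 (edgeR adjusted p = 0.00038 and 0.00077). CKX5 differed by −1.50 ± 0.21, GBSS1, a starch synthase, by −1.65 ± 0.17, and VSP1 by −1.35 ± 0.21 (edgeR adjusted p = 8.6e-06, 2.4e-06 and 6.4e-05). The differences of COP1, VIL1 and HY5 were 0.08, −0.29 and 0.09 (edgeR adjusted p = 0.8, 0.37 and 0.83). The count of 480 fell to 244 and 297 without Col-0 ZT6 replicate 2 or 3, to 274 without Col-0 ZT0 replicate 2, to 303 and 306 without vil1-1 ZT0 replicate 1 or 3, and to 269 and 301 without vil1-1 ZT6 replicate 1 or 2. The share with a more positive effect, 55.4%, was 49.7% without Col-0 ZT0 replicate 1, 48.8% without Col-0 ZT6 replicate 3 and 48.8 to 62.1% over all other settings.

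**Figure D2:**
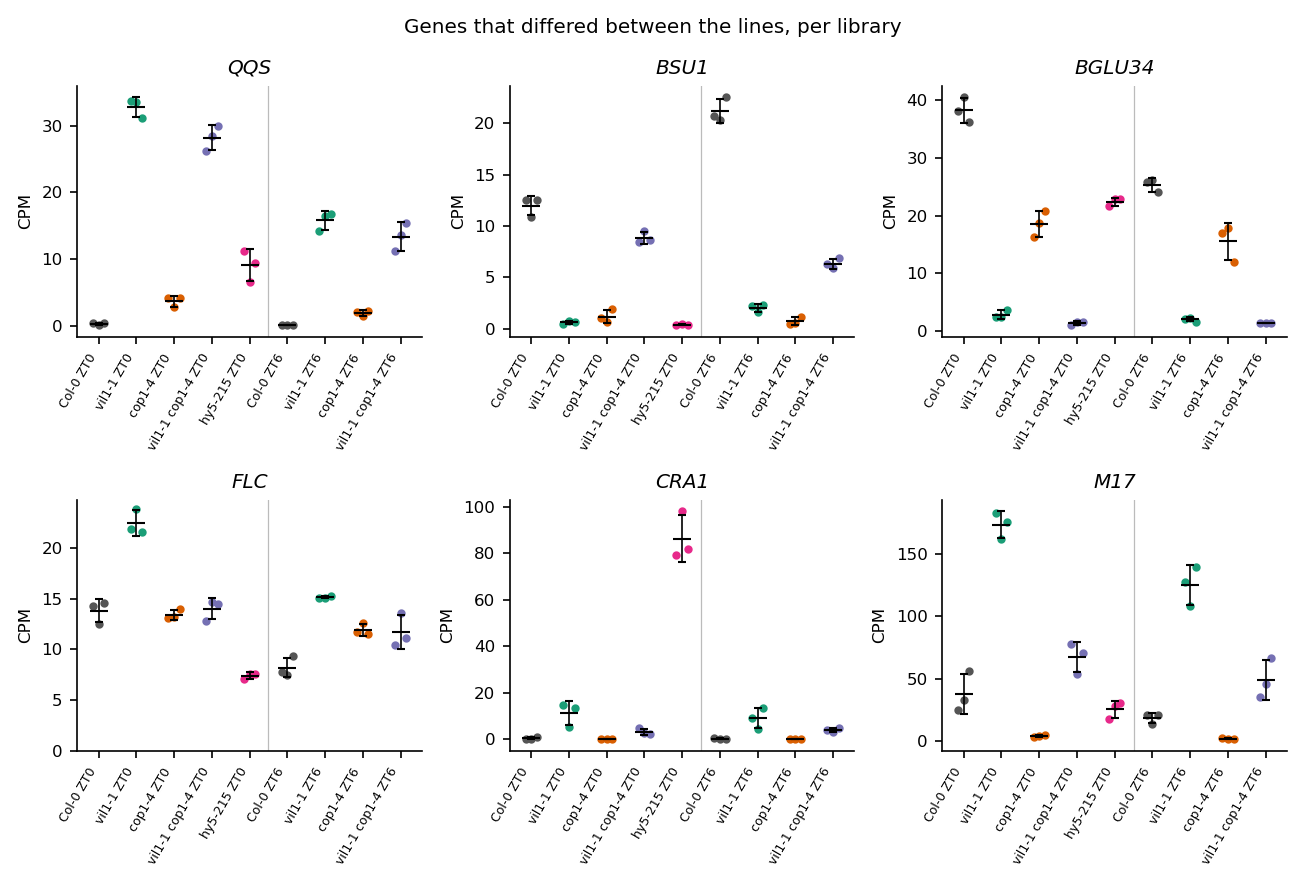
Levels in CPM, on linear axes, of QQS, BSU1, BGLU34, FLC, CRA1 and M17 in each library (points), with the mean and SD of each group (bars, n = 3), ZT0 left and ZT6 right of the grey line. QQS lies at 32.8 CPM in vil1-1 and 0.382 in Col-0 at ZT0, and BSU1 is low in vil1-1, cop1-4 and hy5 but stands at 8.85 in the vil1-1 cop1-4 line.

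cop1-4 was compared with Col-0 to measure what COP1 holds in place at each time. At ZT0 CHS rose 19.3-fold in cop1-4 to 219 ± 6.7 CPM, ELIP2, an early light-induced protein, 46.5-fold and RCA, Rubisco activase, 5.58-fold to 29700 ± 2110 CPM (log2 4.27 ± 0.19, 5.54 ± 0.23 and 2.48 ± 0.06, edgeR adjusted p = 4.9e-14, 1.8e-17 and 3.9e-32). The auxin-response gene IAA29 fell 21.4-fold, and the root iron-uptake genes IRT1 and FRO2 fell 435-fold and 38.5-fold (edgeR adjusted p = 5.6e-28, 2.4e-09 and 1.8e-08). In all 14699 genes changed, 7435 higher and 7264 lower, and of the 5851 that did so at least 2-fold, 2497 were higher and 3354 lower. The 50.6% of changed genes that were higher became 48.5, 48.1 and 47.9% without cop1-4 ZT0 replicate 1, 2 or 3, and 47.9 to 51% over all other settings.

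At ZT0 photoreceptor and COP1-SPA genes rose in 12 of 15 cases in cop1-4 and 1 fell (camera adjusted p = 0.0015; adjusted p = 0.1 with an estimated correlation), with SPA4 3.62-fold, SPA3 2.82-fold and the cryptochrome gene CRY2 2.12-fold higher. Photomorphogenesis regulators rose in 15 of 20 cases and 4 fell (camera adjusted p = 0.0024; adjusted p = 0.1 with an estimated correlation); BBX32 rose 12.2-fold and RUP2, a repressor of UV-B signalling, 3.45-fold, whereas HFR1 fell 2.46-fold. Flavonoid genes rose in 16 of 26 cases and 2 fell (camera adjusted p = 0.0024; adjusted p = 0.21 with an estimated correlation), FLS1 12-fold and MYBL2 6.12-fold higher. The PIF, shade and elongation list had 24 of 31 members lower and 3 higher (camera adjusted p = 2e-05; adjusted p = 0.1 with an estimated correlation), with YUC9, an auxin-synthesis gene, 55.9-fold and ATHB2 5.29-fold lower and PIF7 2.54-fold higher. Auxin genes fell in 20 of 23 cases and 1 rose (camera adjusted p = 1.1e-05; adjusted p = 0.075 with an estimated correlation), LAX3 3.16-fold and GH3.6 2.86-fold lower. All 12 glucosinolate genes fell (camera adjusted p = 0.00014; adjusted p = 0.075 with an estimated correlation); CYP79B3 fell 5.51-fold, and CYP83A1, with 0 reads in cop1-4, was at least 128-fold lower.

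Night and low-energy genes rose in 8 of 11 cases in cop1-4 at ZT0, 9 adjusted over the list alone, and 1 fell (camera adjusted p = 0.0029; adjusted p = 0.34 with an estimated correlation), with DIN10 7.58-fold higher. Light-harvesting and photosynthesis genes split evenly, 11 higher and 11 lower of 26 (camera adjusted p = 0.9): RBCS3B, a Rubisco small subunit, rose 5.93-fold, while LHCB1.4 and LHCB3, antenna proteins, fell 9.53-fold and 3.94-fold. Chlorophyll synthesis genes rose in 7 of 11 cases and 1 fell (camera adjusted p = 0.037; adjusted p = 0.44 with an estimated correlation; adjusted p = 0.097 in a fit of the compared groups alone), HEMA1 2.48-fold higher and PORB 6.3-fold lower. Cell cycle genes fell in 6 of 7 cases (camera adjusted p = 0.031; adjusted p = 0.34 with an estimated correlation). Seed storage and embryo markers fell in 4 of 8 cases (camera adjusted p = 0.067), EM6 25.3-fold and OLE2 50.8-fold. SOC1 rose 9.52-fold, and of the Polycomb and VIN3-like list JMJ30 fell 4.23-fold and SWN, a histone methyltransferase, rose 2.41-fold. Adjusted over the list alone, the other list counts printed for cop1-4 at ZT0 were the same. In cop1-4 at ZT0 the 10 most abundant genes held 10.4 ± 0.419% of the reads in genes and in Col-0 6.82 ± 0.113%.

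At ZT6 11 of 12 glucosinolate genes fell in cop1-4 and 1 rose (camera adjusted p = 1.5e-05; adjusted p = 0.063 with an estimated correlation). CYP79F1 went from 170 ± 34.6 CPM in Col-0 to 0 reads, at least 3500-fold lower, BCAT4 was lower by a ratio of 1210 (counting interval 415 to 5880) and AK3, an aspartate kinase, by a ratio of 1560 (431 to 12800), and MAM1 and CYP83A1 fell 390-fold and 379-fold (edgeR adjusted p = 4.2e-15 and 1.1e-14). CHS and DFR fell 3.53-fold and 39.4-fold (log2 −1.82 ± 0.15 and −5.30 ± 0.32, edgeR adjusted p = 2.4e-09 and 1.9e-18). THA1, threonine aldolase, rose 128-fold, MIOX4, an inositol oxygenase, 109-fold and SEN1, a dark-induced gene, 35.3-fold (edgeR adjusted p = 6.7e-12, 4.3e-23 and 1.3e-11). VSP1, a jasmonate-induced storage protein, fell 22-fold. In all 14277 genes changed, 6993 higher and 7284 lower; among the 4578 that changed at least 2-fold 1481 were higher and 3097 lower. Of all changed genes 49% were higher, but 53, 53.3 and 52.3% without cop1-4 ZT6 replicate 1, 2 or 3, 52.9% with DESeq2 size factors and 48.8 to 53.3% over all other settings.

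Flavonoid genes fell in 22 of 26 cases in cop1-4 at ZT6 and 2 rose (camera adjusted p = 2.6e-05; adjusted p = 0.11 with an estimated correlation), LDOX 23.3-fold and GSTF12 39.6-fold. Night and low-energy genes rose in 10 of 11 cases (camera adjusted p = 6.3e-07; adjusted p = 0.11 with an estimated correlation), TPS11 3.39-fold and TPS10 3.01-fold. Cell cycle genes fell in 7 of 7 cases (camera adjusted p = 0.00026; adjusted p = 0.11 with an estimated correlation). Cold genes fell in 8 of 10 cases and 1 rose (camera adjusted p = 0.0075; adjusted p = 0.12 with an estimated correlation), COR15A 7.89-fold. Defence genes fell in 7 of 11 cases and 1 rose (camera adjusted p = 0.038; adjusted p = 0.11 with an estimated correlation). Auxin genes fell in 19 of 23 cases, 20 adjusted over the list alone, and 2 rose (camera adjusted p = 2.6e-05; adjusted p = 0.085 with an estimated correlation). Clock genes rose in 19 of 30 cases and 4 fell (camera adjusted p = 0.0042; adjusted p = 0.11 with an estimated correlation), with TOC1 2.01-fold and RVE4 3.06-fold higher. Flowering-time genes rose in 9 of 15 cases (camera adjusted p = 0.0096; adjusted p = 0.085 with an estimated correlation), with TEM1, a repressor, 6.03-fold and SOC1, an activator, 3.03-fold higher. Gibberellin and brassinosteroid genes fell in 8 of 11 cases and 1 rose (camera adjusted p = 0.038; adjusted p = 0.11 with an estimated correlation). Counts of the lists other than auxin were the same adjusted over the list alone.

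The effects of cop1-4 at ZT0 and ZT6 correlated with Pearson's r = 0.708 and Spearman's rho = 0.679 across genes, with no shared library; r was 0.552 with no filter on low counts and 0.745 in a fit of the compared groups alone. Of 11064 genes called at both times, 4881 were higher at both, 4668 lower at both and 1515 opposite, where independent lists would share 2424.1 and 2466.9. The test of the difference between the times called 10000 genes, 4476 with a more positive and 5524 with a more negative effect at ZT6. This balance turned with the setting: the share with a more positive effect, 44.8%, was 52.4% with DESeq2 size factors, 53.3% with a stricter filter, 52.2 to 53.4% without any single 1 of the 6 cop1-4 libraries and 44 to 53.4% over all other settings. CHS differed by −6.09 ± 0.24 on the log2 scale, FLS1 by −4.78 ± 0.31 and ELIP1 by −4.47 ± 0.36 (edgeR adjusted p = 5.5e-14, 6.4e-11 and 3.7e-10). Flavonoid genes had a lower effect at ZT6 in 22 of 26 cases and a higher one in 0 (camera adjusted p = 4.2e-11; adjusted p = 0.045 with an estimated correlation). Photomorphogenesis regulators had a lower effect at ZT6 in 15 of 20 cases and a higher one in 2 (camera adjusted p = 0.00022; adjusted p = 0.084 with an estimated correlation), RUP2 by −1.66 ± 0.13. PIF, shade and elongation genes had a higher effect in 17 of 31 cases and a lower one in 4, or 18 and 5 adjusted over the list alone (camera adjusted p = 0.00029; adjusted p = 0.26 with an estimated correlation), with IAA29 at 2.75 ± 0.32. Night genes had a higher effect in 9 of 11 cases (camera adjusted p = 6e-05; adjusted p = 0.35 with an estimated correlation). Adjusted over the list alone, the counts of the flavonoid, regulator and night lists were the same. COP1 differed by −1.06 ± 0.11, VIL1 by −0.47 ± 0.13 and HY5 by −0.49 ± 0.13 (edgeR adjusted p = 2.7e-11, 0.0029 and 0.0017).

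**Figure D3:**
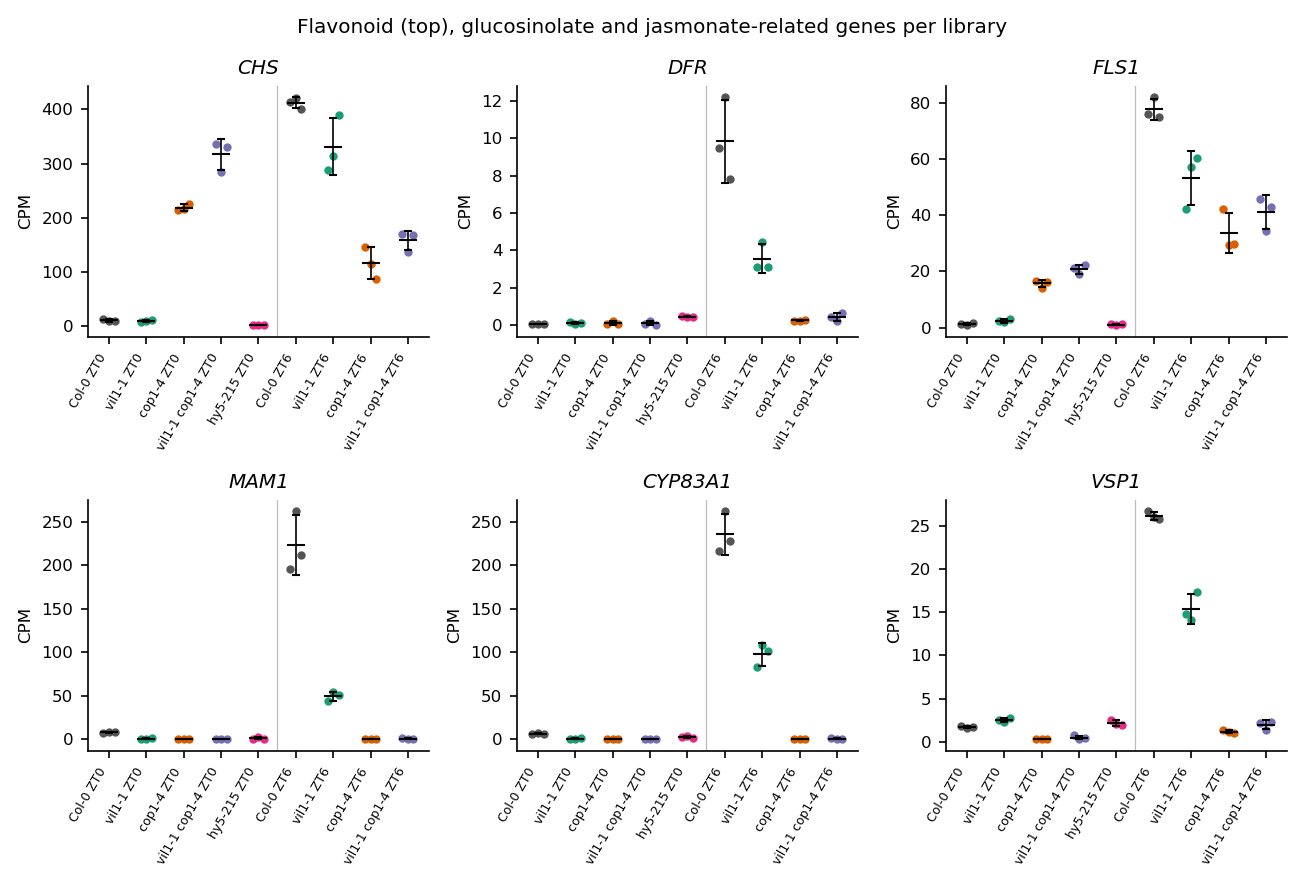
Levels in CPM, on linear axes, of CHS, DFR, FLS1, MAM1, CYP83A1 and VSP1 in each library (points), with the mean and SD of each group (bars, n = 3), ZT0 left and ZT6 right of the grey line. CHS rises from 11.3 to 412 CPM between ZT0 and ZT6 in Col-0 and goes from 219 to 117 in cop1-4.

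The vil1-1 cop1-4 line was compared with Col-0 to measure the joint effect of both mutations. At ZT0 CHAT was at least 740-fold higher than in Col-0, ELIP2 rose 251-fold to 135 ± 0.908 CPM and QQS rose 71.5-fold (log2 7.97 ± 0.20 and 6.16 ± 0.23, edgeR adjusted p = 3.4e-22 and 3.3e-21 for the last pair). IAA29 fell 25.3-fold and IRT1 194-fold (edgeR adjusted p = 1.6e-28 and 2.4e-09). At ZT6 THA1 rose 175-fold and BCB 113-fold (edgeR adjusted p = 1.8e-12 and 8.4e-12), MAM1 fell 318-fold, and CYP79F1 was lower by a ratio of 13900 (counting interval 2500 to 550000). In total 14693 genes changed at ZT0 (7454 higher, 7239 lower) and 14074 at ZT6 (6962 higher, 7112 lower). At ZT0 50.7% were higher, but 49.1, 49 and 49% without vil1-1 cop1-4 ZT0 replicate 1, 2 or 3 and 48.5 to 51.1% over all other settings. At ZT6 49.5% were higher, but 52.2, 52.3 and 51.9% without vil1-1 cop1-4 ZT6 replicate 1, 2 or 3, 50% without Col-0 ZT6 replicate 3 and 49.1 to 52.8% over all other settings. Auxin genes fell in 20 of 23 cases at ZT0 and in 21 at ZT6 (camera adjusted p = 1.3e-06 and 5.3e-07; adjusted p = 0.084 and 0.08 with an estimated correlation). Flavonoid genes rose in 17 of 26 cases and fell in 3 at ZT0 (camera adjusted p = 0.0016; adjusted p = 0.24 with an estimated correlation), and rose in 3 and fell in 20 at ZT6 (camera adjusted p = 0.00036; adjusted p = 0.16 with an estimated correlation). The counts of these lists were the same adjusted over the list alone.

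Adding vil1-1 to cop1-4 was measured by setting the vil1-1 cop1-4 line against cop1-4. At ZT0 the late-embryogenesis gene M17 rose 16.9-fold, the seed peroxiredoxin PER1 10.4-fold and the vicilin-like PAP85 12.6-fold, to 130 ± 6.38 CPM (log2 4.08 ± 0.38, 3.38 ± 0.31 and 3.66 ± 0.36, edgeR adjusted p = 2.4e-07, 1.5e-07 and 4.8e-07). QQS rose 7.55-fold, BGLU34 fell 14-fold and GLP9, a germin-like protein, fell 23.3-fold (edgeR adjusted p = 2.5e-14, 4.7e-18 and 2.9e-09). SOC1 fell 2.22-fold and EMF1 1.62-fold (edgeR adjusted p = 3.4e-11 and 3.2e-09), and FLC changed by 0.06 ± 0.10 (edgeR adjusted p = 0.72). Seed storage and embryo markers rose in 5 of 8 cases, 7 adjusted over the list alone (camera adjusted p = 2.3e-06; adjusted p = 0.096 with an estimated correlation), EM6 6.97-fold. Cold genes rose in 5 of 10 cases, 6 adjusted over the list alone (camera adjusted p = 0.00012; adjusted p = 0.096 with an estimated correlation), KIN2 1.84-fold. In all 3723 genes changed, 2008 higher and 1715 lower; at least 2-fold changes were higher in 658 and lower in 240.

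At ZT6 all 10 cold genes rose against cop1-4 (camera adjusted p = 3.7e-09; adjusted p = 0.01 with an estimated correlation), COR15B 5.98-fold to 96.5 ± 6.64 CPM and COR15A 4.01-fold (edgeR adjusted p = 4.6e-12 and 3.9e-09). Defence genes rose in 7 of 11 cases (camera adjusted p = 0.00064; adjusted p = 0.03 with an estimated correlation), WRKY70, a regulator of salicylate responses, 4.68-fold and VSP2 2.07-fold. Glucosinolate genes rose in 5 of 12 cases (camera adjusted p = 0.00011; adjusted p = 0.034 with an estimated correlation), and those named, CYP79B3 (1.84-fold), CYP79B2 (2.42-fold), CYP83B1 (1.82-fold) and MYB51 (2.05-fold), belong to the indolic branch. Seed storage and embryo markers rose in 7 of 8 cases (camera adjusted p = 4.3e-07; adjusted p = 0.03 with an estimated correlation), EM6 8.47-fold and CRA1 18-fold, to 4.07 ± 1 CPM. M17 rose 26.1-fold and MAF5 5.02-fold, and CBR, a cytochrome b5 reductase, fell 3.75-fold (edgeR adjusted p = 2.7e-07, 5.6e-09 and 4.9e-28). These 4 counts did not differ when adjusted over the list alone. At ZT6 3827 genes changed, 2182 higher and 1645 lower, with 658 higher and 68 lower at least 2-fold. That count was 2344 without cop1-4 ZT6 replicate 3 and 2395 in a fit of the compared groups alone, and the share of higher genes, 57%, was 49 and 47.8% without cop1-4 ZT6 replicate 1 or 2, 47.7% without vil1-1 cop1-4 ZT6 replicate 1, 51.9% with DESeq2 size factors and 67.6% in the fit of the compared groups. COP1 changed by 0.01 at ZT0 and −0.08 at ZT6, VIL1 by −1.70 ± 0.11 and −1.67 ± 0.10, and HY5 by −0.09 and −0.22 (edgeR adjusted p = 0.96, 0.52, 1.5e-15, 5.5e-16, 0.53 and 0.12). Without vil1-1 cop1-4 ZT6 replicate 3 the last was −0.37 with edgeR adjusted p = 0.016.

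Whether the effect of vil1-1 differed between Col-0 and cop1-4 was tested as an interaction. At ZT0 BSU1 differed most among the genes the rule names: it fell in vil1-1 alone, stood at 1.19 ± 0.621 CPM in cop1-4 and at 8.85 ± 0.599 in the vil1-1 cop1-4 line (log2 7.09 ± 0.29, edgeR adjusted p = 5.4e-22). QQS differed by −3.46 ± 0.34, ORP4C, an oxysterol-binding protein, by −1.96 ± 0.19 and GLP9 by −3.84 ± 0.41 (edgeR adjusted p = 3.1e-08, 1.4e-07 and 2.7e-06). FLC and MAF4 differed by −0.63 ± 0.13 and −1.03 ± 0.23 (edgeR adjusted p = 0.0013 and 0.0021): FLC was at 22.5 ± 1.27 CPM in vil1-1 and 13.8 ± 1.16 in Col-0, and at 14 ± 1.04 in the vil1-1 cop1-4 line and 13.4 ± 0.45 in cop1-4. Glucosinolate genes had a more positive effect in cop1-4 in 3 of 12 cases, 6 adjusted over the list alone (camera adjusted p = 2.5e-05; adjusted p = 0.059 with an estimated correlation), CYP79B3 by 0.49 ± 0.10. Of that list, CYP79F1, MYB29, BCAT4 and CYP83A1 had 0 reads in cop1-4 at ZT0, so vil1-1 could not lower them further there. The list was not tested without them. The interaction called 1525 genes, 903 more positive and 622 more negative in cop1-4. For the auxin list the median was −0.17 and the mean 0.03, with 8 of 23 members lower and 1 higher, or 9 and 2 adjusted over the list alone (camera, lower, adjusted p = 0.033; adjusted p = 0.54 with an estimated correlation). That call was lost at ZT0 without Col-0 replicate 2 (camera adjusted p = 0.084), vil1-1 replicate 1 or 2 (0.092 and 0.055), cop1-4 replicate 2 or 3 (0.077 and 0.086) or vil1-1 cop1-4 replicate 1 (0.063).

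At ZT6 the interaction called 3273 genes, 1879 more positive and 1394 more negative in cop1-4; the 57.4% more positive became 48.8% without vil1-1 cop1-4 ZT6 replicate 1 and 48.8 to 61.5% over all other settings. BSU1 differed by 6.51 ± 0.27 and QQS by −3.81 ± 0.44 (edgeR adjusted p = 1.6e-21 and 3.4e-07). Glucosinolate genes had a more positive effect in 9 of 12 cases, 11 adjusted over the list alone (camera adjusted p = 3.4e-10; adjusted p = 0.0031 with an estimated correlation), SUR1 by 1.11 ± 0.11 and CYP79B2 by 1.83 ± 0.28 (edgeR adjusted p = 1.7e-08 and 0.00015). Defence genes did so in 8 of 11 cases (camera adjusted p = 5.2e-06; adjusted p = 0.004 with an estimated correlation), WRKY70 by 2.95 ± 0.34 and VSP1 by 1.53 ± 0.24. Flavonoid genes did so in 14 of 26 cases, 18 adjusted over the list alone, with 1 the other way (camera adjusted p = 1.4e-07; adjusted p = 0.074 with an estimated correlation), UGT75C1 by 1.81 ± 0.24. Night and low-energy genes had a more negative effect in 9 of 11 cases (camera adjusted p = 4.7e-09; adjusted p = 0.076 with an estimated correlation), DRM1 by −1.06 ± 0.14. FLC differed by −0.92 ± 0.14 and MAF4 by −1.49 ± 0.24 (edgeR adjusted p = 5.7e-06 and 1.9e-05). Counts of the defence and night lists were the same adjusted over the list alone. In cop1-4 at ZT6 the glucosinolate genes CYP79F1 and BCAT4 had 0 and 3 reads, so vil1-1 could hardly lower them further there. That floor alone would make the interaction positive for such members, and the list was not tested without them. COP1, VIL1 and HY5 differed by 0.02, −0.04 and −0.10 at ZT0 and by −0.16, 0.29 and −0.32 at ZT6 (edgeR adjusted p = 0.97, 0.94, 0.71, 0.34, 0.18 and 0.097), HY5 at ZT6 by −0.47 with adjusted p = 0.017 without vil1-1 cop1-4 ZT6 replicate 3.

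The effects of vil1-1 in Col-0 and in cop1-4 correlated across genes with Pearson's r = 0.307 at ZT0 and 0.305 at ZT6 and Spearman's rho = 0.247 and 0.179, with no shared library. With no filter on low counts r was 0.157 at both times, and in a fit of the compared groups alone 0.437 and 0.359. Of 897 genes called in both at ZT0, 494 were higher in both, 298 lower in both and 105 opposite, where independent lists would share 104.3 and 82. At ZT6 the 1275 shared genes fell into 643, 301 and 331, against 226.2 and 174.6.

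The hy5 line was compared with Col-0 at ZT0 to measure what HY5, a bZIP activator of light-induced genes, holds in place at the end of the night. Elongation and auxin genes were high: IAA19 rose 5.43-fold to 30.2 ± 4.2 CPM, YUC8 3.44-fold and IAA29 2.3-fold (edgeR adjusted p = 7.5e-16, 9.4e-15 and 4.2e-15; log2 2.44 ± 0.15 and 1.78 ± 0.13 for the first pair). HYH, the homolog of HY5, fell 2.68-fold, CHS 4.7-fold and MYB12, an activator of flavonol synthesis, 6.14-fold (edgeR adjusted p = 8.8e-18, 4.1e-06 and 3.2e-06). BSU1 fell 28.5-fold to 0.417 ± 0.0432 CPM, while QQS rose 23.3-fold and ORP4C 9.51-fold (edgeR adjusted p = 1.9e-21, 3.4e-15 and 2.5e-16). BSU1 was also lower and QQS higher in vil1-1 and cop1-4 at ZT0, so these changes are not particular to hy5. The transposable elements SADHU8-1 and SADHU3-1 had 0 reads in Col-0 and 35 ± 1.58 and 11.7 ± 4.02 CPM in hy5, at least 896-fold and 300-fold higher. In all 8369 genes changed, 4291 higher and 4078 lower, and of the 1510 that did so at least 2-fold, 1007 were higher and 503 lower. Among the higher genes were all 213 otherwise silent genes described below, and 59 other pseudogenes rose at least 2-fold. Whether these go with loss of HY5 was not tested.

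The PIF, shade and elongation list had 25 of 31 members higher and 1 lower in hy5 (camera adjusted p = 4e-08; adjusted p = 0.074 with an estimated correlation), and the auxin list 16 of 23 higher and 2 lower (camera adjusted p = 4.7e-06; adjusted p = 0.074 with an estimated correlation), with IAA7 2.31-fold higher. Light-harvesting and photosynthesis genes rose in 20 of 26 cases and fell in 3 (camera adjusted p = 2.4e-09; adjusted p = 0.36 with an estimated correlation), LHCA1 2.17-fold and LHCA4 2.09-fold. Chlorophyll synthesis genes rose in 9 of 11 cases (camera adjusted p = 1e-04; adjusted p = 0.33 with an estimated correlation), PORB 2.81-fold. Flavonoid genes fell in 8 of 26 cases and rose in 2 (camera adjusted p = 0.068), PAL2 1.56-fold lower and DFR 8.06-fold higher. Clock genes fell in 13 of 30 cases and rose in 5 (camera adjusted p = 0.095), CCA1 1.39-fold lower. Seed storage and embryo markers rose in 7 of 8 cases (camera adjusted p = 2e-05; adjusted p = 0.074 with an estimated correlation), with CRA1 193-fold higher at 86.2 ± 10.2 CPM and CRC higher by a ratio of 592 (counting interval 203 to 2870). FLC fell 1.87-fold and SOC1 rose 1.81-fold (edgeR adjusted p = 9.6e-10 and 4.3e-06). Adjusted over the list alone, the counts of these lists were the same.

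Reads from otherwise silent genes were found in hy5. Reads in no gene made up 2.49 ± 0.372% of its tables and 1.05 ± 0.0717% in Col-0 at ZT0, and reads placed at several sites 4.79 ± 0.572 and 3.38 ± 0.183% (n = 3). Among 9858 genes with at most 24 reads over the 24 libraries of the other lines, 213 had at least 1 CPM in each hy5 library. The same measure gave 0 genes in each of the other 8 groups. Lines other than hy5 were sampled at both times, and a gene read at both is not silent outside either group. The 0 was thus nearly fixed by the design and does not show that such reads are particular to hy5. Of the 213 genes, 177 (83.1%) were annotated as pseudogenes, as were 36.9% of the silent genes. Chromosomes 1, 3 and 4 held 198 of them (93%) and 59.7% of the silent genes. By chromosome, 2.28% of the silent genes were read on chromosome 1, 0.546% on 2, 2.66% on 3, 5.83% on 4 and 0.233% on 5. OFP9, an ovate-family gene, was the only one with a symbol besides SADHU8-1; it stood at 35.2 ± 0.736 CPM, higher than in Col-0 by a ratio of 1350 (counting interval 374 to 11200).

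**Figure D4:**
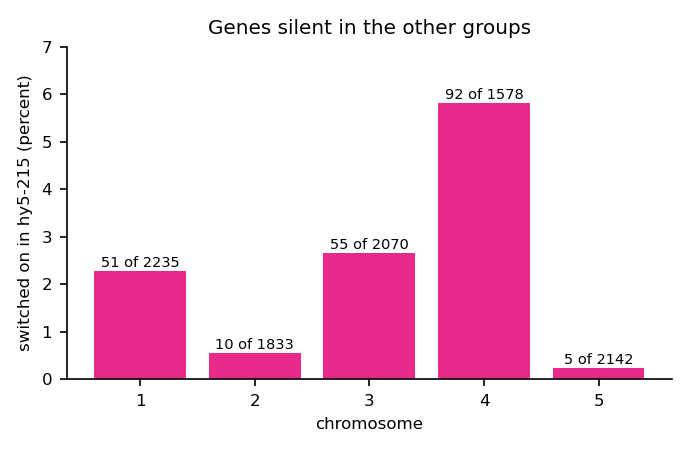
Percent of the silent genes of each chromosome that reached 1 CPM in each hy5 library, with the number of such genes and of silent genes above each bar. The bar is lowest for chromosome 5 (5 of 2142, 0.233%) and highest for chromosome 4 (92 of 1578, 5.83%).

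HY5 acts below COP1, so the effects of cop1-4 and hy5 were set side by side. At ZT0, where both comparisons use the same 3 Col-0 libraries, Pearson's r across genes was 0.011, Spearman's rho −0.045 and the covariance 0.0189; simulated unchanged groups against those controls gave r = 0.473 and a covariance of 0.0149. With no filter on low counts r was 0.114. Of 6183 genes called in both, 1324 were higher in both, 1370 lower in both and 3489 opposite. Independent lists would share 1487.5 higher and 1381.1 lower. The same sign was found in 43.6% of the shared genes, so more of them moved in opposite directions than in the same one. No expected number of opposite genes was computed. IAA29 and CHS were among those that moved in opposite directions. With cop1-4 at ZT6, which shares no library with hy5, r was −0.008 and rho −0.03, and 46.3% of 6096 shared genes had the same sign. The effect of cop1-4 at ZT0 and the ZT6 change of Col-0, which share the Col-0 ZT0 libraries, had r = 0.041, rho = 0.01 and a covariance of 0.0596, against simulated values of 0.486 and 0.0149; r was 0.155 with no filter on low counts. With the ZT6 change of vil1-1, which shares no library, r was 0.021 and rho −0.002. The 3 Col-0 libraries of a time are too few to split, so part of an excess in covariance may come from the shared controls. In the simulations the shared controls gave a positive r, which goes toward the same sign and not toward opposite ones.

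Of 340 list tests by camera over the 17 contrasts, 132 were called with the preset correlation and 8 of these held with an estimated correlation. They were cold response, defence, glucosinolate synthesis and seed storage in the vil1-1 cop1-4 line against cop1-4 at ZT6, defence and glucosinolate synthesis in the interaction at ZT6, flavonoid synthesis in the interaction of cop1-4 with time, and photomorphogenesis regulators between the times in the vil1-1 cop1-4 line. For glucosinolate synthesis in the interaction, some members were near 0 reads in cop1-4, as said above.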

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

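The tests of other splits and of each explanation below were chosen only after the results were seen, except the test of chromosome segments, whose prediction was written first. The interaction of vil1-1 and cop1-4 called 1525 genes at ZT0 and 3273 at ZT6, which differ between the lines. The effect of the mutation differed between the times in 480 genes for vil1-1 and in 10000 for cop1-4. Without Col-0 ZT6 replicate 2 or 3 the 480 became 244 and 297, without Col-0 ZT0 replicate 2 274, without vil1-1 ZT0 replicate 1 or 3 303 and 306, and without vil1-1 ZT6 replicate 1 or 2 269 and 301. In reads that enter no gene count, hy5 stood above Col-0 at ZT0, with a mean of 2.494% against 1.05% for reads in no gene and 4.788% against 3.378% for reads placed at several sites.

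Other splits of the compared libraries were fitted with the compared groups alone. For the interaction of vil1-1 and cop1-4 the real split gave 1788 genes at ZT0 and 2999 at ZT6, and the highest of the other splits gave 276 and 1088. For cop1-4 with time the values were 9863 and 7775. In these 3 cases 1 of 40 splits, the real one, gave as many genes. The other splits mixed libraries of lines that differ. They do not stand for groups without an interaction, so they cannot exclude chance. For vil1-1 with time the real split gave 1111 genes and another 1209, so 2 of 40 gave as many. The same limit holds there: chance was not excluded, and the 1209 does not measure what chance would give. Comparisons of 3 against 3 libraries have 10 splits, too few for a share under 0.05. In those the real split gave 15392, 15052, 12674 and 13287 genes between the times in Col-0, vil1-1, cop1-4 and the vil1-1 cop1-4 line. Against Col-0 it gave 2811 and 5809 genes for vil1-1 at ZT0 and ZT6, 14285 and 13693 for cop1-4, 14492 and 13760 for the vil1-1 cop1-4 line, and 8494 for hy5. The highest other split was 0 in each of these. The vil1-1 cop1-4 line against cop1-4 gave 3309 genes at ZT0 and 2395 at ZT6, with 0 and 1 as the highest other.

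BSU1, SADHU3-2, QQS and BGLU34 had levels that depended on the line: SADHU3-2 was at 1.8 ± 0.25 CPM in Col-0, 8.46 ± 0.37 in vil1-1, 5.07 ± 0.763 in cop1-4 and 2.89 ± 0.284 in the vil1-1 cop1-4 line at ZT0 (n = 3). For BGLU34 reads shared with its paralog are argued against, since BGLU35 gained 3.11 CPM where BGLU34 lost 35.5, or 8.75%; shared reads were not tested for BSU1, SADHU3-2 and QQS. For a variant segment linked to the VIL1 locus, 0 of the 4 genes lay within 100 tested genes of VIL1. Among the 201 genes within that reach 2 changed at least 2-fold, VIL1 itself among them, with 4.13 expected (ratio 0.484). This argues only against a short segment that acts on the genes inside it, and a longer one was not tested. For BSU1 and SADHU3-2 vil1-1 had opposite effects in Col-0 and in cop1-4 (interactions of 7.09 and −3.04 on the log2 scale at ZT0), which is how they were noticed, and whether loss of VIL1 is their cause was not tested. For QQS and BGLU34, which moved the same way in both backgrounds (BGLU34 by −3.81 in cop1-4), loss of VIL1 and a variant carried along with vil1-1 cannot be told apart, because both lines carry vil1-1 and no label gives the crosses behind them; neither accounts for QQS in lines without vil1-1, 9.47-fold higher in cop1-4 and 23.3-fold in hy5.

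In hy5, 213 genes that were silent in the other lines were read, 177 of them pseudogenes. Genomic DNA in the libraries would raise silent genes of every chromosome alike. Against that, the percent read at 1 CPM or more was 2.28, 0.546, 2.66, 5.83 and 0.233% on chromosomes 1 to 5. A looser cut took genes with 0 reads in the other lines. Of these, 149 of 1433, 84 of 1189, 161 of 1314, 212 of 1051 and 92 of 1403 had a read in hy5. A thin share of genomic DNA below 1 CPM is thus not argued against. A loss of HY5 that acts alike on silent pseudogenes of every chromosome would give them equal shares. Those shares were 6.31, 1.04, 5.67, 11.6 and 0.668%. Between chromosomes 4 and 5 the ratios were 25 and 17.4, but this pair was picked as the highest and lowest. The argument against both explanations rests on the spread over all 5 and covers only genes read at 1 CPM or more. Chromosome segments that lost silencing in this seed stock remain possible. Of the other pseudogenes that rose at least 2-fold, 49 of 59 (83.1%) lay on chromosomes 1, 3 and 4. Those chromosomes held 64.7% of the 207 other tested pseudogenes. They were picked from the 213 genes of the same libraries, so the share says only that further pseudogenes follow the same pattern. Any cause with that chromosome pattern would give it. Whether such a loss goes with the hy5 mutation, with this stock or with a batch was not tested, as 1 line holds it.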

How the results depend on the processing

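The fit without the hy5 libraries was chosen after seeing the data. Of 244 counts of changed genes under other settings, 234 lay within 1.5 times the reported value. The exceptions were the vil1-1 cop1-4 line against cop1-4 at ZT6 (3827 genes) and vil1-1 with time (480 genes). In a fit of the compared groups alone these were 2395 and 1111, and leaving out single libraries gave 2344 (without cop1-4 ZT6 replicate 3) to 3875 and 244 (without Col-0 ZT6 replicate 2) to 593; the cause was not tested. For vil1-1 with time, leaving out Col-0 ZT0 replicate 2 gave 274, vil1-1 ZT0 replicate 1 or 3 303 and 306, Col-0 ZT6 replicate 3 297, and vil1-1 ZT6 replicate 1 or 2 269 and 301. With an estimated correlation between genes, 8 of the 132 list calls were made. Of 46 values of the relations under other settings 11 moved. With no filter on low counts Pearson's r became 0.261 for vil1-1 at both times, 0.552 for cop1-4 at both times, 0.157 for vil1-1 in Col-0 and in cop1-4 at either time, 0.114 for cop1-4 and hy5 and 0.155 for cop1-4 and the ZT6 change of Col-0. Without hy5 it became 0.616 for vil1-1 at both times and 0.336 for vil1-1 in both backgrounds at ZT0, and in a fit of the compared groups alone 0.677 and 0.437 for these and 0.745 for cop1-4 at both times. The cause was not tested. Of 8188 values of single genes, 8098 kept their direction and side of the threshold, 83 lost the call and 7 gained one; of 1715 values of single lists, 1632 kept theirs and 83 lost the call. The median log2 change of all genes shifted by at most 0.087, for cop1-4 with time without cop1-4 ZT6 replicate 1. Shares of higher genes near 50% passed it under some settings: 49% for cop1-4 against Col-0 at ZT6 became 52.9% with DESeq2 size factors and 52.4% with a stricter filter, and 44.8% for cop1-4 with time 52.4 and 53.3%. Removal of the organelle genes changed no value, as they had 0 reads.

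With the replicate number as a block, vil1-1 against Col-0 gave 2092 and 4423 genes at ZT0 and ZT6, cop1-4 14657 and 14221, and the vil1-1 cop1-4 line 14639 and 14047. Against cop1-4 that line gave 3642 and 3699, the interaction of both mutations 1482 and 3150, vil1-1 and cop1-4 with time 425 and 9897, and hy5 8264. Between the times Col-0, vil1-1, cop1-4 and the vil1-1 cop1-4 line gave 15182, 14703, 13594 and 13738. The call of the photoreceptor and COP1-SPA list in the vil1-1 cop1-4 line against cop1-4 at ZT6 (camera adjusted p = 0.045; adjusted p = 0.32 with an estimated correlation) was lost, with adjusted p = 0.053; without cop1-4 ZT6 replicate 3 it was 0.16. Across 36 pairs of groups, libraries of the same number correlated by −0.0817 to 0.0878 after removal of group means, so the numbers do not pair the libraries. Depth limits genes with few reads, for which bounds or counting intervals stand in place of fitted values.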

Other observations

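Tests of the seed storage pattern below were chosen only after the results were seen. Root markers fell in 7 of 13 cases and 1 rose in cop1-4 against Col-0 at ZT0 (camera adjusted p = 0.17), with CASP1, which organises the Casparian strip, 4.42-fold lower, at 7.6 ± 1.42 CPM against 33.8 ± 2.94 (n = 3). In the vil1-1 cop1-4 line against cop1-4 at ZT0 3 of 13 rose (camera adjusted p = 0.0086; adjusted p = 0.4 with an estimated correlation), with XTH14, a root-hair wall enzyme, 2.6-fold and EXPA18, an expansin, 2.25-fold higher. Of 8 stomatal lineage genes 3 rose and 1 fell in cop1-4 against Col-0 at ZT0 (camera adjusted p = 0.93), where KAT1, a guard-cell potassium channel, fell 4.79-fold. The counts of these lists were the same adjusted over the list alone.

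Some seed storage genes were higher in vil1-1 than in Col-0 at ZT0, and most members of that list were higher in hy5. CRA1 was at 11.2 ± 5.09 CPM in vil1-1 and 86.2 ± 10.2 in hy5, against 0.434 ± 0.402 in Col-0 (n = 3). The 2S albumins SESA2 and SESA3 had 5 and 4 reads in Col-0 and 1 each in vil1-1. RNA of ungerminated seeds as 1 source in both lines is argued against: vil1-1 had 2.94 CRC reads per 100 CRA1 reads at ZT0 (0 to 4.86 over libraries) and hy5 26.7 (24.1 to 30.4), a ratio of 9.09; vil1-1 had 6.1 at ZT6 (1.95 to 10.6). The vil1-1 cop1-4 line had 32.5 at ZT0 (27.9 to 38.1), near the hy5 value, so the ratio does not set that line apart from hy5. In vil1-1 at ZT0 the value rests on 28 CRC reads. Seed material of another kind in hy5 would raise M17, PER1 and LEA18 too, which changed there by −0.59, −0.28 and −0.41 (edgeR adjusted p = 0.11, 0.22 and 0.26). M17 changed by −0.82 with edgeR adjusted p = 0.033 without Col-0 ZT0 replicate 1 (0.033 to 0.65 over all other settings), and PER1 had edgeR adjusted p = 0.0095 in a fit of the compared groups alone (0.0095 to 0.43). Levels of 37.9, 23.1 and 36.4 CPM in Col-0 could hide a small share of seed RNA, so such material and expression in the seedlings cannot be told apart.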
